A study of Homo sapiens with 6 samples.

How the data were processed

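RNA from 6 cultures of primary human bronchial epithelial cells was sequenced, 3 untreated and 3 exposed to LPS at 100 ng/ml for 2 h on day 15, after 14 days at the air-liquid interface. Per the labels' protocols, libraries were made with a stranded total RNA kit after depletion of ribosomal RNA. Groups and replicate numbers were taken from the sample labels. The numbers run from 1 to 3 and from 4 to 6, and the labels name no pairing, so the libraries were treated as unpaired. Whether cultures of the 2 groups share a donor is not given, and the labels give no batch or day of preparation.

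The authors deposited a table of FPKM for assembled transcripts in each library. Per the submitters' processing notes, HISAT2 2.10, Cufflinks 2.2.1, Cuffdiff and the GRCh38 build were used, without further roles or settings, and the gene annotation is not given in the sources used here. FPKM divides reads by transcript length and by the mapped total, so read numbers cannot be recovered, the depth per library is unknown, and no counting interval or detection floor is given. The table has 177668 transcripts, of which 65.6% are above 0 in exactly 1 library and 8.1% are above 0 in all 6. A single transcript held 48.6% to 98.6% of the summed FPKM of each library, so totals were not used for scaling. Whether reads were counted by strand is not given in the sources used here. Transcript assembly assigns reads to names and loci before FPKM are computed, so reads of overlapping genes, antisense genes or near-identical copies can end up under either name.

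The authors also deposited a gene-level comparison in the Cuffdiff layout. Per the file headers it gives a log2 fold change, a fold (the ratio of the second to the first condition), a p-value and a q-value for 723 entries, the largest q being 0.0494, so it lists only the authors' calls. Its conditions are named only sample 1 and sample 2. For that reason its FPKM per condition and its test statistic, 3 columns in all, were not used.

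Symbols were taken from the FPKM table, and 257 entries whose symbol had turned into a date were renamed through their transcript identifier. Of 159158 transcript identifiers, 159050 were found in GENCODE release 29 on GRCh38, which supplied gene identifiers, gene types and coordinates (1-based). Transcripts without a name (18510) were left out of gene tests. FPKM were summed per symbol, genes with a mean of at least 1 FPKM over the 6 libraries were kept (15448, of which 2317 were at 0 in 1 or more libraries), and values were analysed as log2(FPKM + 1), so fold changes of low genes are understated. LPS was compared with untreated by limma 3.58.1 in R 4.3.3 (lmFit, eBayes with an intensity trend), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. All 6 libraries entered, with no covariate.

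Gene lists fixed before the data were examined, 29 in number, covered immediate early genes, cytokines and chemokines, NF-kB feedback and targets, TLR4 pathway components, MAPK feedback, EGFR ligands, interferon-stimulated genes, airway antimicrobial defence, long noncoding RNAs of inflammation, heat shock genes, the unfolded protein response, hypoxia genes, glucocorticoid targets, metallothioneins, NRF2 targets, cholesterol synthesis, tight and adherens junctions, proliferation markers, mitochondrial transcripts, replication-dependent histones and reference genes. Markers of basal, ciliated, secretory and squamous cells, ionocytes, fibroblasts, leukocytes and endothelial cells completed them. The 28 lists with at least 3 tested members were tested with limma's camera at a preset correlation of 0.01, beside camera with an estimated correlation and fry, each adjusted over the lists. Members were also adjusted over the list alone.

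The rule for named genes was fixed at the same time. It takes, among genes past the threshold whose groups do not overlap, the 12 with the largest and the 8 with the smallest log2 fold change, leaving out small RNAs by symbol, Y-linked genes and XIST. It adds up to 4 members of each list with the smallest adjusted p, and always FOS, EGR1, ATF3, IL6, CXCL8, CXCL2, CCL20, TNF, NFKBIA, TNFAIP3, ICAM1, TLR4, LY96, CD14, MUC5AC, MUC5B, SCGB1A1, FOXJ1, KRT5 and NEAT1. Where fewer than 5 genes passed in a direction, the 5 with the smallest unadjusted p would have been named as not passing. Some genes that the rule names are not reported here. Genes outside the rule are said to have been chosen after their values were seen, except where a sentence names every member of a list that meets a stated condition.

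The procedure was tested on simulated data with the means and moderated spread of these 15448 genes, drawn from a normal distribution. Genes dropping to 0 in single libraries, as 2317 tested genes and 15 of the 26 that passed did, were not modelled. False calls that arise from such zeros were therefore not measured. Values were drawn independently for each gene, so the simulation does not show how camera behaves when list members are correlated. Genes changed singly were taken only from those with a mean log2(FPKM + 1) above 2, so recovery among lower genes was not measured. Of 100 genes changed by 2 on the log2 scale, 45% were recovered, and of 100 changed by 4, 78%, with 11 false calls among 134. Changes went up or down at random and values below 0 were set to 0. Genes with a mean under 4 that were lowered by 4 thus changed by less than that. A simulated list of 25 genes raised by 1 gave a camera p of 7.92e-24, or 3.59e-04 with an estimated correlation, and an unchanged list 0.641 and 0.698. Alternatives planned in advance were other pseudocounts, filters, scalings, variance models, library weights, thresholds and set tests, omission of small RNAs, and omission of each replicate. Added after the data were seen were genes above 0 in all 6 libraries, the highest transcript in place of the sum, omission of transcripts above 10000 FPKM, and loci in place of symbols (21680 tested). The 10 splits of the 6 libraries into 3 and 3 were refitted. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.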

Results

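The libraries came from primary human bronchial epithelial cells cultured at an air-liquid interface, a condition in which basal cells build a layer that also holds ciliated and secretory cells. After 14 days of differentiation, 3 cultures stayed untreated (replicates 1 to 3). On day 15, 3 others (replicates 4 to 6) received lipopolysaccharide (LPS), the Gram-negative outer membrane component sensed through TLR4, at 100 ng/ml for 2 h. The comparison of the 2 groups asks which transcripts respond early to LPS. Expression was available as FPKM per assembled transcript, with 48184 to 77674 transcripts above 0 per library. Read numbers are not part of these values, so the depth behind them is unknown. Transcripts without a gene name held 98.6%, 75.2% and 97.6% of the summed FPKM in the untreated libraries and 1.42%, 1.94% and 1.03% in the LPS libraries, and they did not enter the gene comparisons. In the untreated libraries nearly all of this was 1 transcript, with 98.3%, 75.1% and 97.5% of the summed FPKM, whose locus did not pass limma (adjusted p = 0.0786). In each LPS library 1 transcript likewise held 48.6%, 95.1% and 98.6% of the summed FPKM. These shares exceed the unnamed ones, so the largest transcript there carries a name. After transcripts were summed by gene symbol, 15448 genes had a mean of at least 1 FPKM and were tested. Across these genes, which are not independent replicates, log2(FPKM + 1) correlated at 0.704 to 0.727 between libraries of a group and at 0.686 to 0.712 between groups. The labels name no separate donors or days for the replicates, so the p-values measure only the spread between these samples, which may be technical.

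Inflammatory signalling genes were higher as groups in the LPS libraries. The list of cytokines and chemokines rose with a median log2 fold change of 0.94 on the log2(FPKM + 1) scale, and the list of NF-kB feedback genes and targets rose with a median of 0.97. In limma's camera test with a preset correlation between genes, the adjusted p was 1.11e-10 for the cytokines and 1.99e-13 for the NF-kB list. Neither list passed with a correlation estimated from these libraries (adjusted p = 0.222 with an estimated correlation for both). The fry test, which asks only whether the members of a list move one way on balance, gave an adjusted p of 0.0326 for each. No other list of the 28 tested passed camera.

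IL36G, an epithelial interleukin-1 family cytokine, went from 3.04 ± 1.53 FPKM in untreated cultures to 23.99 ± 9.09 FPKM with LPS (SD, n = 3 each), a 7.88-fold difference. IL1B was at 1.66 ± 0.57 FPKM untreated and 11.85 ± 5.49 FPKM with LPS, a 7.15-fold difference, and IL1A at 2.28 ± 0.95 and 12.6 ± 3.99 FPKM, a 5.54-fold difference. IL33 of the same family, chosen after its values were seen, had means of 8.32 and 10.2 FPKM and did not pass. IL36A was listed at 0 in the 3 untreated libraries and at 3.51, 3.85 and 2.45 FPKM in the LPS libraries. IL1A, IL1B, IL36G and IL36A lie in that order on chromosome 2 of GRCh38, between positions 112773915 and 113008044. CSF3, the granulocyte colony-stimulating factor, chosen after its values were seen, had a mean of 3.97 FPKM untreated and 16.9 FPKM with LPS, and the neutrophil chemokine CXCL2 4.44 ± 1.29 and 13.5 ± 2.59 FPKM, which is 3.04-fold. IL6 was at 2.74 ± 0.64 FPKM untreated and 5.71 ± 0.43 FPKM with LPS, or 2.09-fold.

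Of the 30 cytokines and chemokines, 24 were tested and 21 had a fold change above 0. In 12 of the 24, every LPS library lay above every untreated library. Non-overlap in either direction arises in 10% of genes by chance and was seen in 12.8% of all tested genes. When adjusted over the list alone, 9 members passed limma and all of them rose: IL36A, IL36G, IL1A, IL1B, CSF3, CXCL2, CXCL5, IL19 and IL6. Over all genes tested, 0 members passed at an adjusted p under 0.05. The smallest limma adjusted p was 0.109, for IL36A (log2 fold change 2.08 ± 0.25 SE). IL36A passed without LPS replicate 6 (limma adjusted p = 0.0478) and when genes with a mean of at least 0.3 FPKM were tested (limma adjusted p = 0.0489).

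Several well known LPS targets varied widely between libraries. CXCL8, which encodes interleukin-8, was at 83.4, 7.72 and 273 FPKM in the untreated libraries and at 86.3, 16.03 and 45.8 FPKM in the LPS libraries (log2 fold change -0.51 ± 1.37 SE, limma adjusted p = 0.950). CCL20 was at 31.6, 47.9 and 10.5 FPKM untreated and at 373, 131 and 24.2 FPKM with LPS (limma adjusted p = 0.838). CXCL1, chosen after its values were seen, was at 15.2 to 23.1 FPKM untreated and at 409, 41.2 and 34.4 FPKM with LPS. TNF stayed below the mean of 1 FPKM needed for the test: it was listed at 0 in the 3 untreated libraries and at 0.45, 0.34 and 0.33 FPKM with LPS.

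The NF-kB list held 28 genes, of which 26 were tested and 24 had a fold change above 0. Every LPS library lay above every untreated library for 16 of the 26. Adjusted over the list alone, 12 members passed limma and rose: TNIP3, CD83, RELA, SOD2, TNFAIP2, NFKBIB, NFKBIE, NFKB1, TNIP1, IRAK2, ZC3H12A and NFKB2. As with the cytokines, 0 of them passed over all genes tested. CD83, a surface protein of activated antigen-presenting cells, was at 0.93 ± 0.32 FPKM untreated and 19.5 ± 11.7 FPKM with LPS (SD, n = 3 each), a 20.96-fold difference. TNIP3, a partner of the NF-kB inhibitor A20, was at 2.51 ± 0.52 and 10.13 ± 2.103 FPKM, which is 4.04-fold. SOD2, the mitochondrial superoxide dismutase, was among the abundant members, at 201.7 ± 46.1 FPKM untreated and 551 ± 136 FPKM with LPS, which is 2.73-fold. NF-kB subunits themselves were included, with RELA at 3.31 ± 0.39 and 7.38 ± 0.83 FPKM (2.23-fold) and NFKB1, chosen after its values were seen, at a mean of 38.6 and 79.5 FPKM.

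**Figure D1:**
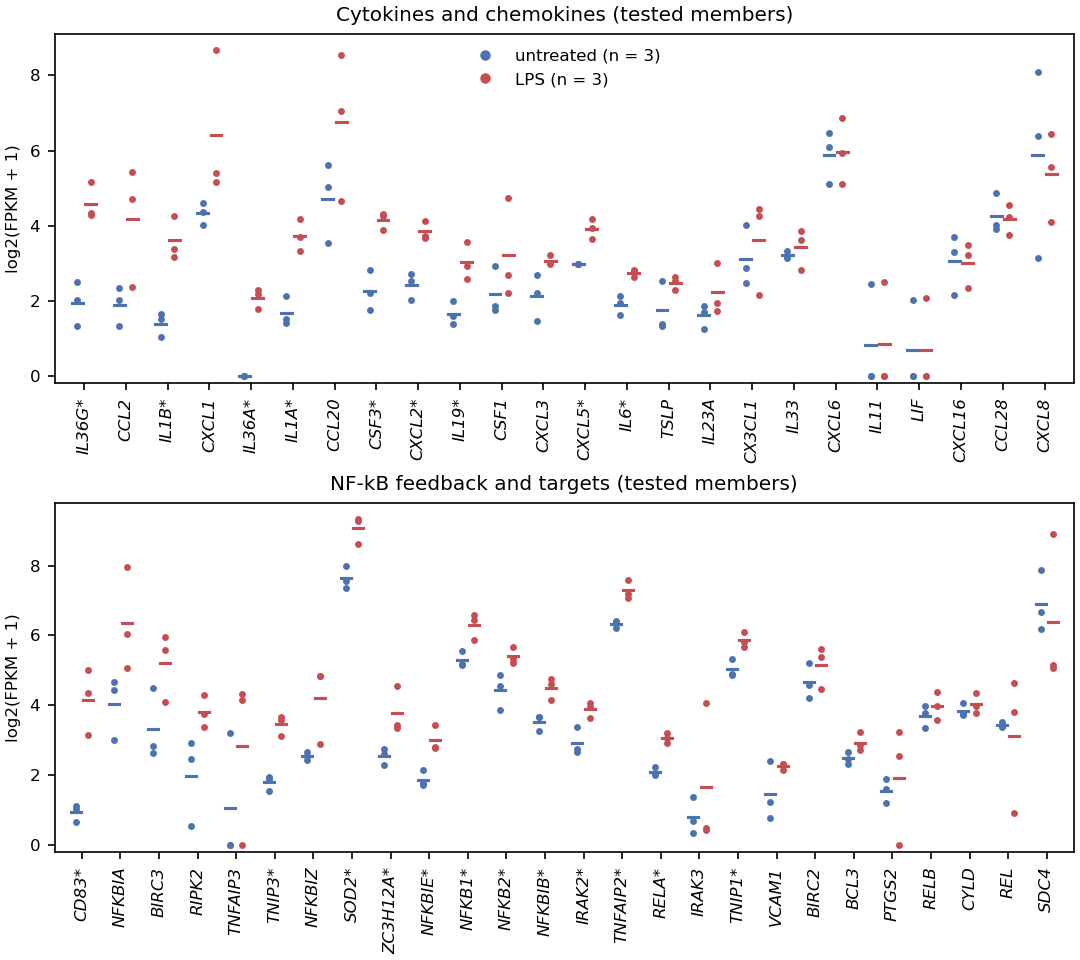
Each point is the log2(FPKM + 1) of one library for the tested members of the cytokine and chemokine list (upper panel) and of the NF-kB list (lower panel), blue for the 3 untreated and red for the 3 LPS libraries, with short bars at the group means. Asterisks mark the 9 and 12 members that passed limma when adjusted over the list alone, such as IL36G and CD83, while members such as CXCL8 and TNFAIP3 show libraries of a group far apart.

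The inhibitor gene NFKBIA was at 7.04, 20.8 and 24.4 FPKM untreated and at 65.4, 32.6 and 250.5 FPKM with LPS (log2 fold change 2.33 ± 0.86 SE, limma adjusted p = 0.838). TNFAIP3, which encodes A20, was listed at 0, 0 and 8.29 FPKM untreated and at 19.2, 16.7 and 0 FPKM with LPS. The adhesion molecule gene ICAM1, on chromosome 19 from 10270835 to 10286615, had at most 2.56 FPKM in any library and was not tested. Transcripts that carry the name of the overlapping gene AC011511.2, chosen after their values were seen, were at 1.61, 0.87 and 2.12 FPKM untreated and at 85.6, 52.4 and 2.0 FPKM with LPS.

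Immediate early genes as a list missed the threshold (limma's camera, adjusted p = 0.0545), with 16 of 25 tested members above 0. The fry test gave an adjusted p of 0.0419, and camera 0.567 with an estimated correlation. A single member, FOSL2, passed over all genes and also when adjusted over the list alone. FOSL2 encodes the AP-1 subunit FRA2 and lies on chromosome 2 from 28392448 to 28417312. It was listed at 0 in the 3 untreated libraries and at 24.98, 33.95 and 23.49 FPKM with LPS (log2 fold change 4.81 ± 0.22 SE, limma adjusted p = 0.00367). With all transcripts of its loci summed it was at 6.31, 0.66 and 6.84 FPKM untreated and at 50.4, 46.7 and 54.96 FPKM with LPS (3.50 on the log2 scale), and no locus of FOSL2 passed. FOS was at 2.79 ± 0.59 FPKM untreated and 1.46 ± 0.99 FPKM with LPS, and ATF3 at 6.31 ± 2.15 and 5.58 ± 2.07 FPKM (limma adjusted p = 0.838 and 0.936). EGR1 had means of 0.92 and 0.38 FPKM and was not tested. The serum response factor gene SRF was at 11.2 ± 1.78 and 18.0 ± 3.11 FPKM.

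The list of EGFR ligands gave the same camera adjusted p of 0.0545, with 6 of 7 members above 0. When adjusted over the list alone, HBEGF and EREG passed limma and rose, while 0 passed over all genes. HBEGF was at 6.09 ± 1.41 FPKM untreated and 21.6 ± 3.50 FPKM with LPS, which is 3.56-fold, and EREG at 4.51 ± 0.77 and 24.4 ± 12.9 FPKM, which is 5.41-fold. TGFA was at 9.51 ± 7.43 and 4.62 ± 6.58 FPKM. The EGFR ligand list passed camera without untreated replicate 3 (adjusted p = 0.0239) and without LPS replicate 4 (adjusted p = 0.0469). With all 6 libraries its camera adjusted p was 0.567 with an estimated correlation, and fry gave 0.371. For the unfolded protein response list the camera adjusted p was again 0.0545, with 13 of 16 members above 0 and 0 members past limma, adjusted over the list alone or over all genes. SDF2L1, an endoplasmic reticulum chaperone partner, was at 15.3 ± 15.0 and 51.5 ± 12.1 FPKM and TRIB3, a pseudokinase of the stress response, at 1.85 ± 0.84 and 3.73 ± 0.25 FPKM. This list passed camera without LPS replicate 5 (adjusted p = 0.0266) and without LPS replicate 6 (adjusted p = 0.0166). With all 6 libraries its camera adjusted p was 0.567 with an estimated correlation, and fry gave 0.404.

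The receptor pathway that senses LPS showed no change that passed a test. The TLR4 pathway list had a median log2 fold change of 0.20 and a camera adjusted p of 0.257. TLR4 itself had mean log2 values 0.12 ± 1.20 SE apart, and its co-receptor LY96 was at 2.28 ± 0.36 FPKM untreated and 3.33 ± 1.66 FPKM with LPS (limma adjusted p = 0.993 and 0.845). CD14 had means of 0.83 and 0.64 FPKM and was not tested. IRAK1, a kinase downstream of the receptor, was at 11.4 ± 1.73 and 18.3 ± 1.77 FPKM (limma adjusted p = 0.750). MAPK feedback genes had a camera adjusted p of 0.990, with a median of -0.08, a mean of 0.04 and the test pointing down. The phosphatase gene DUSP5 of that list was at 3.37 ± 0.60 and 6.62 ± 1.07 FPKM. Interferon-stimulated genes were split evenly, 12 above and 12 below 0 (limma's camera, adjusted p = 0.973). ISG20 was at 10.6 ± 3.45 and 16.3 ± 2.26 FPKM, and IRF1 was listed at 30.7, 15.6 and 0 FPKM untreated and at 22.3, 78.6 and 22.7 FPKM with LPS. In these 3 lists 0 members passed, adjusted over the list alone or over all genes.

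Airway antimicrobial genes had 8 of 20 tested members above 0 (limma's camera, adjusted p = 0.828). The protease inhibitor elafin, PI3, was at 16.4 ± 0.75 FPKM untreated and 29.7 ± 10.5 FPKM with LPS. DEFB4A, which encodes beta-defensin 2, was listed at 0 in the 3 untreated libraries and at 43.7, 0 and 33.4 FPKM with LPS, and it passed limma without LPS replicate 5 (adjusted p = 0.0207). Long noncoding RNAs of inflammation had a camera adjusted p of 0.844, with a median of 0.09 and a mean of 0.08 while the test pointed down. NEAT1 was at 45.7 ± 5.12 and 36.9 ± 10.6 FPKM, and SNHG1 at 12.7 ± 4.28 and 5.29 ± 0.31 FPKM (limma adjusted p = 0.838 and 0.670). MALAT1, an abundant nuclear RNA chosen after its values were seen, was listed at 0 in untreated replicates 2 and 3 and in LPS replicate 6. Because RNAs that most cells hold, such as MALAT1, also appear at 0, a gene at 0 is described only as listed at 0. In both lists 0 members passed, adjusted over the list alone or over all genes.

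Lists of stress and metabolism did not pass. The camera adjusted p was 0.973 for heat shock genes, 0.990 for hypoxia genes, 0.786 for glucocorticoid targets, 0.257 for metallothioneins, 0.973 for NRF2 targets and 0.990 for cholesterol synthesis. In each of these 6 lists 0 members passed limma, adjusted over the list alone or over all genes. The heat shock gene HSPA1B was at 78.6, 47.7 and 0.29 FPKM untreated and at 0.31, 0.22 and 0.23 FPKM with LPS. It passed as lower with LPS once untreated replicate 3, its low untreated library, was left out (limma adjusted p = 0.0213). For heat shock genes the median was 0.10, the mean -0.09 and the test pointed up, and for cholesterol synthesis the median was 0.01, the mean -0.15 and the test pointed down. MT2A, a metallothionein that is also a glucocorticoid target, was at 221 ± 37.9 FPKM untreated and 448 ± 176 FPKM with LPS. The small heat shock protein gene HSPB1 was at 4.82 ± 0.80 and 9.72 ± 3.42 FPKM. SLC7A11, the cystine transporter among the NRF2 targets, was at 16.97, 9.81 and 21.2 FPKM untreated and at 1.31, 1.86 and 9.68 FPKM with LPS. At locus level, a setting chosen after the data were seen, a locus of SLC7A11 passed (log2 fold change -3.29 ± 0.19 SE, limma adjusted p = 0.00614). It was at 10.2, 7.6 and 8.7 FPKM untreated and listed at 0 in the 3 LPS libraries. The glycolytic enzyme gene LDHA was at 69.3 ± 3.01 and 92.2 ± 29.96 FPKM.

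**Figure D2:**
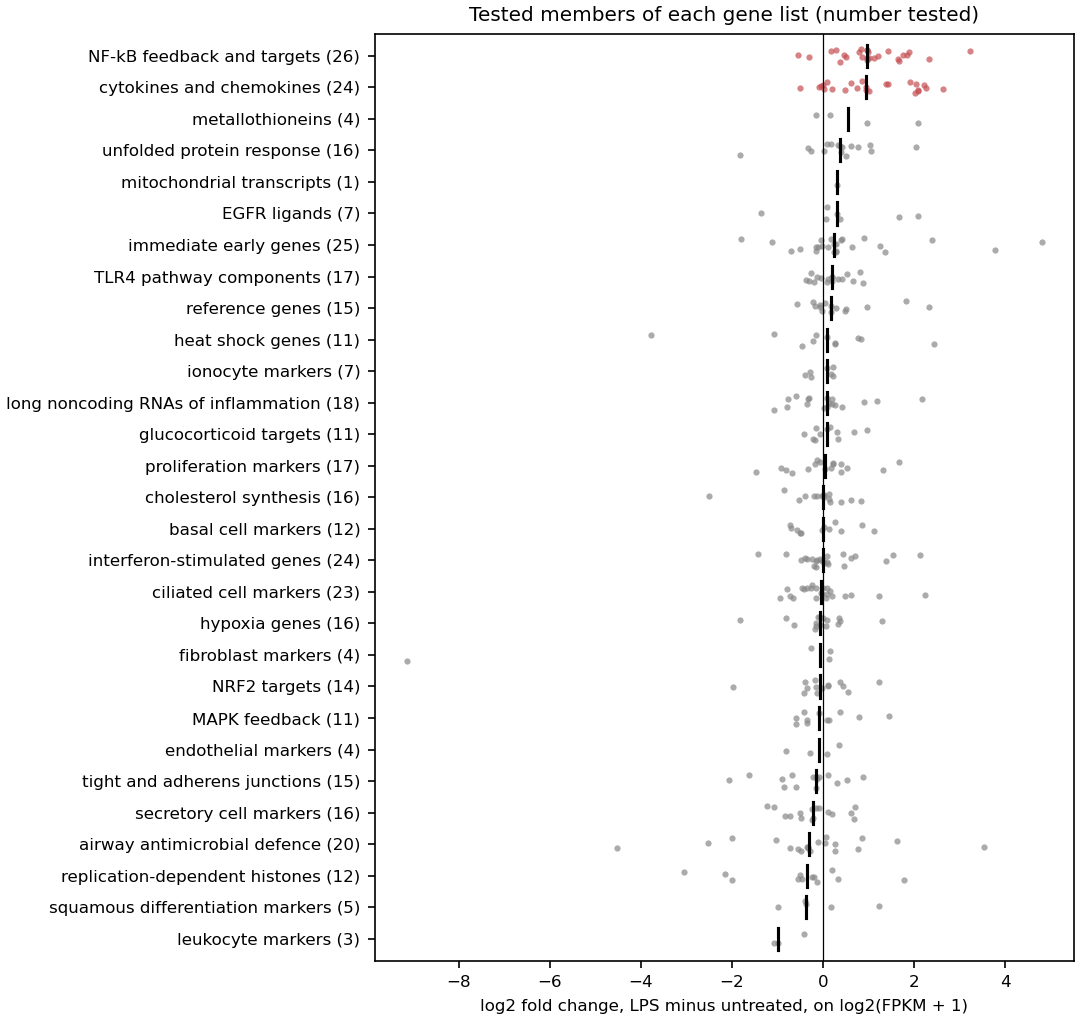
Each point is the log2 fold change (LPS minus untreated, log2(FPKM + 1) scale) of a tested member of one fixed gene list, with a tick at the list's median; red marks lists with a camera adjusted p under 0.05. The cytokine and NF-kB lists, with medians of 0.94 and 0.97, are the lists in red, and neither passed with an estimated correlation (adjusted p = 0.222).

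Markers of the epithelial cell types did not separate the groups with the settings reported here. The camera adjusted p was 0.973 for basal, 0.786 for ciliated, 0.257 for secretory, 0.973 for ionocyte and 0.828 for squamous differentiation markers, and 0.274 for tight and adherens junctions. In these 6 lists 0 members passed limma, adjusted over the list alone or over all genes. Secretory markers passed camera, pointing down, with the highest transcript per gene, a setting chosen after the data were seen (adjusted p = 0.0247). With the settings reported here and an estimated correlation their camera adjusted p was 0.832. KRT5, the basal keratin, was at 152 ± 16.7 FPKM untreated and 129.7 ± 93.5 FPKM with LPS. FOXJ1, the regulator of ciliated cells, was listed at 0 in untreated replicate 2 and LPS replicate 6 and at 58.7 to 366 FPKM in the other libraries. The club cell secretoglobin SCGB1A1 was at 748 ± 430 and 353.4 ± 19.03 FPKM. The mucin genes MUC5B and MUC5AC were at 9.49 ± 4.58 and 4.02 ± 2.41 FPKM and at 1.41 ± 0.29 and 3.21 ± 2.13 FPKM (limma adjusted p = 0.838 for both). MUC16, a membrane mucin, was at 11.9 ± 2.80 and 4.61 ± 1.80 FPKM (limma adjusted p = 0.635). The squamous keratin KRT6B had means of 4.72 and 12.3 FPKM. For ionocyte markers the median was 0.09, the mean -0.04 and the test pointed down.

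Markers of cells outside the epithelium were few. Leukocyte markers had 5 of 18 members listed and 3 tested, all 3 with a fold change below 0 (limma's camera, adjusted p = 0.104). Without LPS replicate 6 the adjusted p of the list was 0.0167. With all 6 libraries it was 0.567 with an estimated correlation, and fry gave 0.37. LAPTM5, one of the 3, was at 10.2 ± 0.82 FPKM untreated and 5.11 ± 4.17 FPKM with LPS. Fibroblast and endothelial markers, with 4 tested members each, had camera adjusted p values of 0.786 and 0.973. COL6A3 was listed at 13156, 0 and 13622 FPKM in the untreated libraries and at 0 in the 3 LPS libraries, passing limma without untreated replicate 2 (adjusted p = 4.17e-04), while COL1A1, another fibroblast collagen, was at 2.57 ± 0.40 and 2.08 ± 1.11 FPKM. Proliferation markers had an adjusted p of 0.990 and replication-dependent histones 0.524. HIST1H1B was listed at 24.4, 21.25 and 0 FPKM untreated and at 0 in the 3 LPS libraries. It passed limma as lower with LPS once untreated replicate 3, its untreated library at 0, was left out (adjusted p = 0.0185). Of the mitochondrial transcripts, MT-ND6 alone of 15 was listed, at 124 ± 65.1 and 148 ± 56.7 FPKM, so that list was not tested. Reference genes had an adjusted p of 0.257, and for 4 of the 15 every LPS library lay above every untreated one. YWHAZ was at 34.5 ± 16.4 and 198.9 ± 131 FPKM, a 5.77-fold difference, TFRC at 29.2 ± 3.43 and 41.4 ± 2.78 FPKM, ACTB at 83.4 ± 19.5 and 180.0 ± 110 FPKM, and RPLP0, chosen after its values were seen, at means of 205 and 204 FPKM. In all of these lists 0 members passed limma, adjusted over the list alone or over all genes.

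For single genes, limma passed 26 of 15448 at an adjusted p under 0.05, 14 higher and 12 lower with LPS. At an unadjusted p under 0.05 there were 835 genes, 464 higher and 371 lower. That is 5.4% of all tested genes, close to the share of 0.05 that would arise with no change at all. Genes listed at 0 in a whole group made up 10 of the 26, and for these the size of the log2 fold change depends on the pseudocount. With 3 libraries against 3, an exact permutation test of one gene cannot go below a two-sided p of 0.1. The count fell to 11 without untreated replicate 2, and it was 54 without untreated replicate 1 and 46 without untreated replicate 3 (24 lower). Without LPS replicates 5 or 6 there were 28 or 32 higher genes, and 7 lower genes without LPS replicate 6. Among genes above 0 in all 6 libraries, a setting chosen after the data were seen, 10 passed.

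The 12 genes with the largest increases included the chromatin reader BRD2, the RNA helicase DDX5 and the endothelial and immediate early gene APOLD1. BRD2, on chromosome 6 from 32968660 to 32981505, was listed at 0 in the 3 untreated libraries and at 83.3, 50.4 and 57.6 FPKM with LPS (log2 fold change 5.99 ± 0.24 SE, limma adjusted p = 0.00325). DDX5, on chromosome 17 from 64499616 to 64508199, went from 6.50 ± 1.26 to 129 ± 24.3 FPKM, a 19.9-fold increase (4.11 ± 0.23 SE on the log2 scale, limma adjusted p = 0.00728). Transcripts named APOLD1, a gene on chromosome 12 from 12725917 to 12829975, went from 1.17 ± 0.07 to 31.4 ± 1.46 FPKM, a 26.8-fold increase under that name (3.90 ± 0.17 SE, limma adjusted p = 0.00325). With all transcripts of their loci summed, the log2 fold change was 1.91 for BRD2, 3.95 for DDX5 and 0.02 for APOLD1. BANF1, a DNA-bridging protein of the nuclear envelope, went from 5.40 ± 1.41 to 79.1 ± 15.9 FPKM, a 14.7-fold increase. TCTA was listed at 0 in the 3 untreated libraries and at 33.5, 24.6 and 28.9 FPKM with LPS, PCNP at 0 and at 32.1, 16.9 and 48.2 FPKM, and the RNA-binding protein gene RBM38 at 0 and at 14.8, 9.93 and 11.5 FPKM. HINT3, C2orf74 and AP000275.2 were each listed at 0 in at least 1 untreated library and rose with log2 fold changes of 4.95, 3.92 and 6.30, of which 4.52, 0.70 and 0.60 were left when all transcripts of their loci were summed. PIGCP2, a processed pseudogene, was listed at 0 untreated and at 213, 2015 and 275 FPKM with LPS (limma adjusted p = 0.0487), a call lost in 10 of 19 other settings, against 5 for HINT3 and 4 for PCNP.

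Among the genes that passed, the largest decrease was that of MIR181A1HG, the host transcript of microRNA-181a on chromosome 1 from 198807493 to 198937429. It stood at 251, 298 and 619 FPKM in the untreated libraries and at 0.72, 0.74 and 0.77 FPKM with LPS (log2 fold change -7.69 ± 0.37 SE, limma adjusted p = 0.00427). KLF5, an epithelial Kruppel-like transcription factor on chromosome 13 from 73054976 to 73077542, went from 173 ± 34.5 to 15.3 ± 2.24 FPKM (log2 fold change -3.41 ± 0.23 SE, limma adjusted p = 0.0124). LINC02331, a long noncoding RNA, went from 23.7 ± 3.22 to 0.98 ± 0.65 FPKM, and INTS14, an Integrator complex subunit, from 18.98 ± 5.98 to 0.41 ± 0.29 FPKM. The helicase gene DDX47 was at 28.7, 30.1 and 41.6 FPKM untreated and at 0.39, 0 and 0.48 FPKM with LPS. SAMD15, PQBP1 and AC068831.1 were listed at 0 in the 3 LPS libraries and at 7.64 to 18.8 FPKM in the untreated ones. With all transcripts of their loci summed, the log2 fold change was -0.06 for DDX47, -0.33 for INTS14 and -1.55 for AC068831.1, and it turned to 0.08 for SAMD15 and 0.18 for PQBP1. The call was lost in 7 of 19 other settings for SAMD15 and AC068831.1, in 5 of 19 for PQBP1, in 6 of 20 for LINC02331 and in 5 of 20 for INTS14. Outside the fixed rule, RBM47, an RNA-binding protein gene, went from a mean of 30.1 to 240.6 FPKM, and C1orf50 also rose. UCK1, SIRT5, PELI2 and TIMM17B fell, and these 6 were named after their values were seen.

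Some of these genes share an assembled locus with transcripts of other names. When every transcript of a gene's loci was summed whatever its name, 11 of the 26 genes kept at least 0.85 of their log2 fold change, among them DDX5, BANF1, KLF5, TCTA, LINC02331 and MIR181A1HG. For TCTA, LINC02331 and MIR181A1HG the summed values equal those by name (share 1.000). No transcript of another name was added there, so their share could not fall and the sum does not test them. For 8 genes less than 0.2 was left, among them APOLD1 and DDX47, whose annotated intervals on chromosome 12 overlap. At locus level -0.49 was left for UCK1. The locus holding APOLD1 was at 28.9, 30.9 and 33.5 FPKM untreated and at 32.5, 29.8 and 31.9 FPKM with LPS. The share left was 0.727 for FOSL2 and 0.319 for BRD2. The loci of PIGCP2 were at 0, 916 and 2883 FPKM untreated and at 451, 2015 and 275 FPKM with LPS, with a higher untreated mean.

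**Figure D3:**
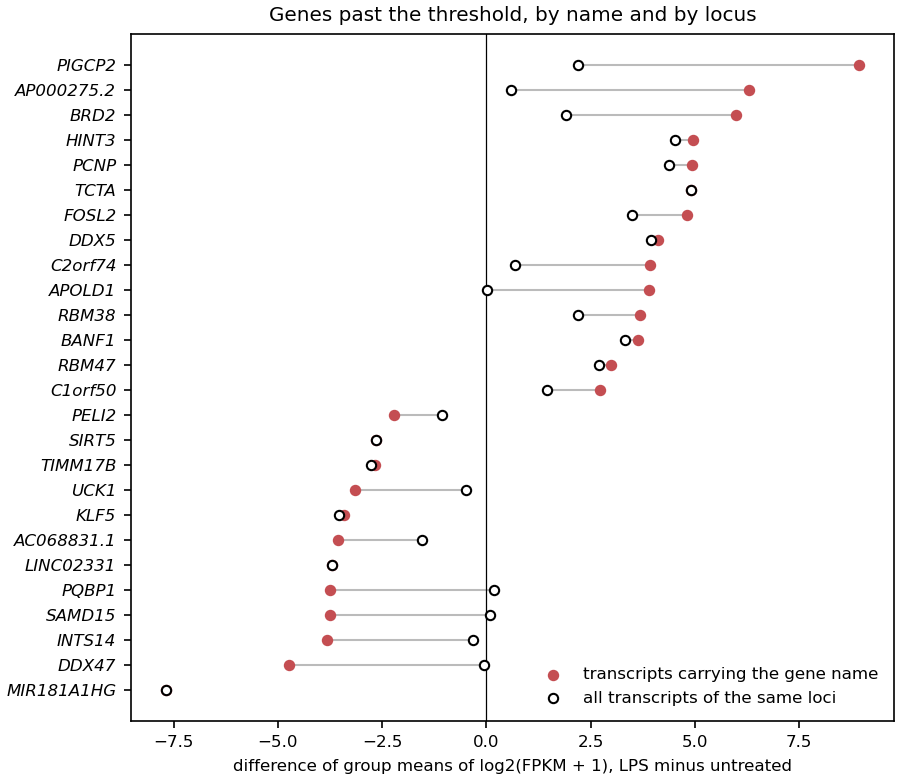
For each of the 26 genes that passed limma, the log2 fold change (LPS minus untreated) of transcripts carrying the gene's name is set beside that of all transcripts of its loci. Genes such as KLF5 and DDX5 keep their fold change, while APOLD1, with 0.004 of it left, and DDX47 lie near 0 at locus level.

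The authors' deposited table of differential expression was set against these FPKM. It is taken to rest on the same libraries, so it is no independent measurement. The authors' deposited table has 723 entries, 472 with a higher and 251 with a lower value in its second condition. Its conditions are labelled only as sample 1 and sample 2, so its fold changes are of the second over the first, and which of them held LPS is not stated. In the authors' deposited table, 16 of the 30 cytokines and chemokines and 21 of the 28 NF-kB genes appeared, all with positive log2 fold changes and with medians of 2.3 and 1.46. IL36G had a 14.6-fold change in the authors' deposited table (log2 fold change 3.87), and the largest of the entries for IL1B and CD83 had log2 fold changes of 3.43 and 3.80. CXCL8 had log2 fold changes of 1.69 and 1.19 in the authors' deposited table, against -0.51 in limma on the FPKM of single libraries. TNF and TNFAIP3 had log2 fold changes of 3.63 and 1.87 in the authors' deposited table, and NFKBIA, with a pair of entries, 1.61 and 1.33. ICAM1 had a log2 fold change of 2.36 in the authors' deposited table, and an entry for AC011511.2 and its neighbours over the same interval had 2.03.

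Other lists were thinner there. The authors' deposited table held 4 EGFR ligands, all higher in the second condition, 4 members of the unfolded protein response, all higher, and 6 immediate early genes, of which 5 were higher and EGR1 had a log2 fold change of -1.25. It also held 4 glucocorticoid targets, 3 antimicrobial genes, 2 MAPK feedback genes, 2 metallothioneins, 2 squamous markers and 1 replication-dependent histone, all higher in the second condition of the authors' deposited table. MT1X and MT2A, which are the 2 metallothioneins and also 2 of the glucocorticoid targets, share 1 entry of the authors' deposited table, and LBP, NOS2, KRT6B, FOSL2, NR4A1 and AC011511.5 appear there only in entries with several names. Interferon-stimulated genes (1 higher, 1 lower) and basal markers (2 higher, 1 lower) went both ways in the authors' deposited table, and the 1 TLR4 pathway gene and the 1 fibroblast marker there were lower. Long noncoding RNAs went both ways there, with MIR3142HG at 2.21 and one of the PVT1 entries at -1.29 in the authors' deposited table, both chosen after their values were seen. Among the cell type lists, ciliated, ionocyte, leukocyte and endothelial markers had 0 entries in the authors' deposited table, and so had reference genes and proliferation markers. MUC16 had a log2 fold change of -0.80 and SCGB1A1 of 0.60 in the authors' deposited table. The SCGB1A1 values above had means of 748 FPKM untreated and 353 FPKM with LPS, the other direction if the second condition is LPS, and did not pass limma.

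Of the 709 symbols in the authors' deposited table, 564 were among the genes tested by limma. If the second condition is LPS, the sign of the fold change was the same for 441 of the 564 (78.2%), and if the first is LPS, for 123. The 441 were made up of 314 of 389 higher and 127 of 175 lower genes. Across these genes, which are not independent replicates, the log2 fold changes of the authors' deposited table and of limma had a Pearson correlation of 0.48 if the second condition is LPS and of -0.48 if the first is. An unadjusted limma p under 0.05 was reached by 143 of the 564 (25.4%), against 5.4% of all tested genes, and 141 of the 143 had the same sign if the second condition is LPS, or 2 if the first is. Over the 564 genes, these values argue against the first condition being LPS, although the headers do not state it. FOSL2 and MIR181A1HG were the 2 genes that passed limma and appear in the authors' deposited table. The entry that holds FOSL2 and its neighbours had a log2 fold change of 0.75 in the authors' deposited table. MIR181A1HG had log2 fold changes of -0.79 and -0.88 in the authors' deposited table, against -7.69 in limma on log2(FPKM + 1).

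**Figure D4:**
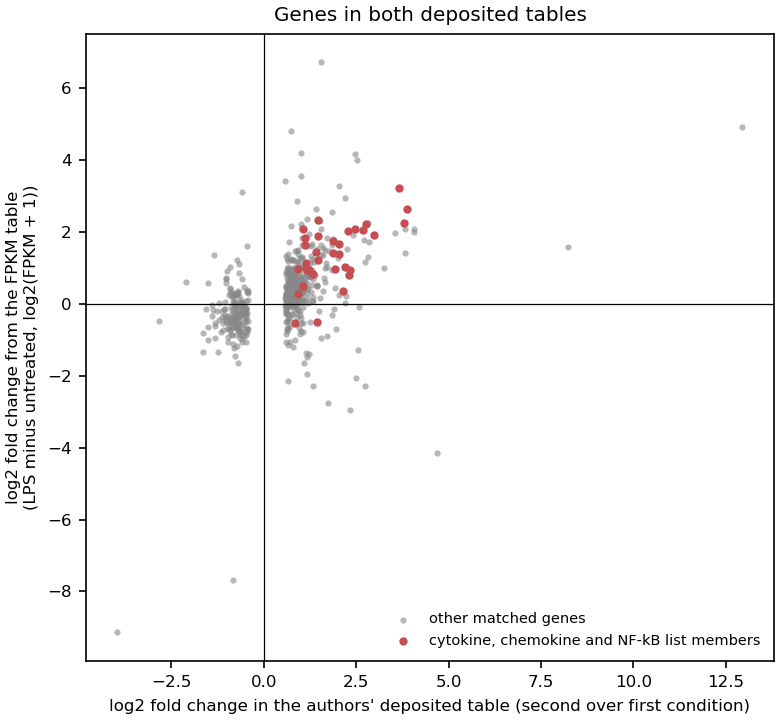
The log2 fold change of each of 564 genes in the authors' deposited table (second over first condition) is plotted against its limma log2 fold change (LPS minus untreated, log2(FPKM + 1) scale). If the second condition is LPS, the sign is shared by 441 genes and the correlation across genes is 0.48, and if the first is LPS, by 123 genes with a correlation of -0.48.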

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

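The test of loci without a gene name was chosen after the table had been examined. Assembled loci that carry no gene symbol stayed out of the comparison of genes, and 637 of them had a mean of at least 1 FPKM. In limma fitted and adjusted over these 637 loci alone, 6 passed an adjusted p of 0.05, 2 higher and 4 lower with LPS, against 37 at an unadjusted p under 0.05. XLOC_033070, 1 of the 4 lower, did not pass when all 21680 loci were tested together. The locus XLOC_037227 was listed at 0 in the 3 untreated libraries and at 14.1, 12.4 and 13.1 FPKM in the LPS libraries, a mean of 13.2 FPKM. The locus XLOC_010337 was listed at 0 untreated and at 40.1, 222 and 80.4 FPKM with LPS, a mean of 114.3 FPKM. Both were listed with LPS only, in transcripts outside the gene comparison. For named genes, as many at 0 in 3 libraries and at 1 FPKM or more in the other 3 (35) were found in another split of the libraries. Such a pattern therefore cannot be told apart from transcripts missing from single assemblies. In the other direction, XLOC_037228 was at 725, 946 and 1554 FPKM untreated and listed at 0 with LPS, and XLOC_006519 was at 843, 1152 and 1223 FPKM untreated and at 10.2, 26.2 and 10.2 FPKM with LPS. XLOC_037227 and XLOC_037228 carry consecutive locus numbers and were listed in opposite groups. Whether their assembled boundaries differ between the groups was not tested.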

How the results depend on the processing

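The settings using genes above 0 in all 6 libraries, the highest transcript, no transcripts above 10000 FPKM and loci were chosen after the data were seen. Under the settings that keep gene symbols, 0 named results that had passed changed direction, while with all transcripts of their loci summed PQBP1 and SAMD15 turned from -3.75 and -3.76 to 0.18 and 0.08. Of the 20 named genes that passed limma, AP000275.2, APOLD1, BRD2, FOSL2, MIR181A1HG and TCTA passed in each setting by symbol in which they were tested (19 for AP000275.2, BRD2, FOSL2 and TCTA, which have libraries at 0, and 20 for the others), but at locus level 0.60 and 0.02 were left of the log2 fold changes of AP000275.2 and APOLD1, and no locus of these 2 or of FOSL2 passed. By symbol, over all 20, the call was lost in 61 of 387 values. PIGCP2 lost it in 10 of 19 settings. Sizes for genes listed at 0 in a whole group depend on the pseudocount. Over the other settings by symbol the log2 fold change ran from 5.61 to 9.29 for BRD2, from 4.66 to 8.09 for FOSL2, from 4.79 to 8.17 for TCTA and from -6.98 to -3.49 for SAMD15. Of 124 named genes that had not passed, 5 passed in some setting by symbol. At locus level a locus of SLC7A11, which had not passed by symbol, also passed (limma adjusted p = 0.00614). The cytokine and NF-kB lists passed in 20 of 20 settings of camera with the preset correlation. The camera adjusted p ran from 7.01e-14 to 3.65e-07 for the cytokines and from 6.81e-16 to 2.01e-09 for the NF-kB list. With the settings otherwise as reported, each list had a camera adjusted p of 0.222 with an estimated correlation. The correlations estimated were 0.1115 and 0.142, against the preset 0.01. The simulated list of independently drawn genes also had a higher camera p with an estimated correlation (3.59e-04 against 7.92e-24). A higher p in that test thus does not by itself show correlated members or the lack of a rise. In no setting did 21 other lists pass. Ionocyte, fibroblast and leukocyte markers had too few members left for a test in some settings.

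The count of 26 genes (14 higher, 12 lower) depended on single libraries, on the feature tested and on adjustment. Leaving out 1 replicate gave 11 to 54 genes, 9 to 32 higher and 2 to 33 lower. Without untreated replicate 2 there were 11 (9 higher, 2 lower, 6 of them among the 26), without untreated replicate 1 there were 54 (33 lower) and without untreated replicate 3 there were 46 (22 higher, 24 lower). Without LPS replicate 5, 28 were higher, and without LPS replicate 6, 32 were higher and 7 lower. The cause was not tested. A mean of at least 5 FPKM left 7 lower genes, with fewer genes tested. Genes above 0 in all 6 libraries gave 10 (4 higher, 6 lower) because genes listed at 0 drop out, and loci gave 64 (39 higher, 25 lower). An unadjusted p under 0.05 gave 835 (464 higher, 371 lower), 5.4% of all tested genes, close to the share of 0.05 that would arise with no change. Other pseudocounts, scalings and variance models gave 22 to 30.

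Lists near the threshold passed in some settings, for causes not tested. With no filter, camera adjusted p values were 0.0181 for immediate early genes, 0.0191 for EGFR ligands and 0.0168 for the unfolded protein response, and with a mean of at least 0.3 FPKM 0.04925, 0.0457 and 0.0335. Quantile normalization gave 0.0331 for immediate early genes and 0.0347 for EGFR ligands, and arrayWeights 0.0370 for each of these 3 lists. The highest transcript per gene gave 0.0245 for immediate early genes, 0.00840 for the unfolded protein response and 0.0247 for secretory markers, genes above 0 in all 6 libraries 0.0121 for the unfolded protein response, and fry 0.0419 for immediate early genes. With an estimated correlation and the settings otherwise as reported, the adjusted p was 0.567 for immediate early genes, EGFR ligands, the unfolded protein response and leukocyte markers and 0.832 for secretory markers. Leaving out 1 replicate gave 0.0239 (untreated replicate 3) to 0.353 (LPS replicate 5) for EGFR ligands, also passing without LPS replicate 4 (0.0469), and 0.0166 (LPS replicate 6) to 0.442 (LPS replicate 4) for the unfolded protein response, also passing without LPS replicate 5 (0.0266). It gave 0.0167 (LPS replicate 6) to 0.295 (untreated replicate 3) for leukocyte markers. With no pseudocount, and if its second condition is LPS, 442 genes shared the sign of the authors' deposited table, against 441. Depth is unknown, so what it limits was not measured.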

Other observations

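The tests of gene counts over other splits, of genes at 0 over other splits, of leukocyte markers and of the largest folds of the authors' deposited table were chosen after the results were seen, and so were the genes of both paragraphs that follow.

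PACERR, a long noncoding RNA next to PTGS2 on chromosome 1 (186680622 to 186681446), was at 3.39 ± 0.81 FPKM untreated and 20.7 ± 3.51 FPKM with LPS (SD, n = 3 each). Its log2 fold change was 2.31 ± 0.23 SE, with a limma adjusted p of 0.0539, over the threshold, and at locus level, a setting chosen after the data were seen, it passed (2.33 ± 0.23 SE, limma adjusted p = 0.0409). PTGS2, the cyclooxygenase-2 gene, was listed at 2.02, 1.29 and 2.71 FPKM untreated and at 0, 8.50 and 4.83 FPKM with LPS, while the authors' deposited table gives it a log2 fold change of 2.14. TNFRSF9, a receptor of the TNF family, was at 1.34 ± 0.48 and 10.5 ± 4.64 FPKM (limma adjusted p = 0.207). The collagenase gene MMP13 was at 29.8 ± 7.23 and 67.6 ± 8.24 FPKM (limma adjusted p = 0.400). ALOX15B, a lipoxygenase gene, was listed at 0 in the 3 untreated libraries and at 3.20, 4.73 and 2.23 FPKM with LPS (limma adjusted p = 0.171). In the authors' deposited table TNFRSF9 had a log2 fold change of 2.82 in its largest entry, MMP13 2.92 and ALOX15B 3.81.

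The basal cell factor TP63 had lower values in the second condition, with log2 fold changes of -0.88 and -1.32 in the authors' deposited table, and MIR944, which lies within TP63, -1.83 in the authors' deposited table. In the FPKM table TP63 was at 7.75, 11.1 and 15.5 FPKM untreated and at 0.26, 15.3 and 17.98 FPKM with LPS (limma adjusted p = 0.893). The atypical cadherin gene FAT2 was at 7.65 ± 1.07 and 3.50 ± 0.59 FPKM (limma adjusted p = 0.4999), against -1.32 in the authors' deposited table. The protease gene ADAMTS15 was at 2.94 ± 1.22 and 0.52 ± 0.32 FPKM (limma adjusted p = 0.635), against -1.66 in the authors' deposited table.

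For the rise of the cytokine list, a difference in scaling shared by all genes of a library is argued against. Over 3 scalings the lowest difference between the median of the cytokine list and that of all tested genes was 0.94 (95% bootstrap interval 0.40 to 1.90). The subtraction by itself takes out a shift shared by all genes, so the 3 scalings are not separate evidence. Leukocytes in the LPS cultures stay open: 0 of the 5 leukocyte markers listed, of 18, had an LPS mean above every untreated library, but only 3 reached a mean of 1 FPKM, and the most abundant, LAPTM5, was at 10.2 FPKM untreated and 5.11 FPKM with LPS, a baseline that can hide a small share. Of the 10 splits of the 6 libraries, 1, the real one, gave a camera p as small for either list. It was 7.92e-12 for the cytokines and 7.09e-15 for NF-kB genes. Over the other splits, which mix the groups, camera p ran from 0.00546 to 0.178 for the cytokines and from 2.58e-04 to 0.438 for NF-kB genes. Small camera p values with the preset correlation thus also arose in mixed groups, and 10 splits are too few for a share under 0.05. A response to LPS stays open, as does correlation between members. Neither list passed camera with an estimated correlation (adjusted p = 0.222). Both passed fry (adjusted p = 0.0326), which allows for correlation between members but does not compare a list with other genes.

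Many of the 26 genes that passed alone may reflect how transcripts were assembled and named. The number of genes at 0 in 3 libraries and at 1 FPKM or more in each of the other 3 was 35 for the real groups, and 2 of the 10 splits, the real one included, reached it, the highest other being 35. That is what would be seen for genes at 0 because transcripts were missing from the assembly of single libraries, for the 10 of the 26 genes at 0 in a whole group. For transcripts of a locus named differently in the groups, the share of the log2 fold change left at locus level was used. Its median was 0.57 (95% bootstrap interval 0.24 to 0.91), with PQBP1 at -0.047 and KLF5 and TIMM17B at 1.04. This cannot be told apart over the 26 genes as a set: less than 0.2 was left for 8 and 0.85 or more for 11. Shares such as that of TCTA, which could not fall, enter the median. Summed over its loci, DDX47 was at 28.7, 30.3 and 41.6 FPKM untreated and at 31.3, 33.0 and 31.2 FPKM with LPS. For DDX47 and APOLD1 the fold change was thus in transcripts of that name and not in the locus total. As many genes as 26 came from 1 of the 10 splits, the real one, the highest other being 15, and the splits are too few for a share under 0.05.

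The largest folds in the authors' deposited table include log2 fold changes of 12.95 for SLBP, 8.24 for TTC27 and 4.70 for IGF2R. In the FPKM table SLBP was at 20.1, 48.5 and 512 FPKM untreated and at 27.2, 81616 and 6551 FPKM with LPS, and TTC27 at 20.9, 331 and 53.6 FPKM and at 14.2, 207 and 3468 FPKM. The highest library, LPS replicate 5, held 92.5% of the summed LPS FPKM of SLBP, with 1 transcript at 70596 FPKM. LPS replicate 6 also lay above every untreated library for SLBP, while LPS replicate 4 lay within their range. Among the untreated libraries 1 held 88.2% of the summed FPKM. How far a few transcripts of one library made these folds stays open. IGF2R was at 4606, 18.5 and 23839 FPKM untreated and at 17.7, 1569 and 12.1 FPKM with LPS, the opposite direction if the second condition is LPS, so the share of an LPS library says nothing of its fold. No biological explanation was tested for these folds.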
